A study of Equus caballus with 6 samples.

How the data were processed

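Small RNA sequencing was performed on testes of the Mongolian horse, with 3 libraries from immature testis and 3 from mature testis. Per the labels' protocols, each library was made from 3 µg of total RNA with a kit that ligates adapters to both ends of small RNAs, and products of 140 to 160 bp were cut from a gel. Neither the age of the animals nor the stage of spermatogenesis is given in the labels. The labels call the libraries replicates of 2 groups of testes but do not state that each came from a separate animal. The p-values therefore measure the spread between these libraries.

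The deposited table holds whole-number read counts per distinct sequence, 1 column per library and not normalized, per the file headers and the values. Bowtie is named per the submitters' processing notes, without a version. The genome build and the step that called a sequence a piRNA are not given in the sources used here. The table lists 4936717 distinct sequences of 25 to 32 nt with 17914237 reads. Its identifiers run up to 13656183, so it is part of a longer list of sequences, and its totals are totals of called piRNAs, not sequencing depth. The name of the table labels its sequences as newly found piRNAs, so piRNAs known before may have been kept apart. All shares and CPM values below are relative to the reads in the table, and the piRNA pool below means these reads. All 6 columns were used, and 0 rows named no sequence.

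The libraries held 1382083, 2347351 and 1462339 reads in immature testis and 4139452, 4032042 and 4550970 reads in mature testis. The table is sparse: 76.95% of the sequences had 1 read in all libraries together, and 17191 sequences were found in all 6 libraries. A count of 0 allows up to 3 reads, which corresponds to 2.17, 1.28 and 2.05 CPM in the immature libraries and to 0.725, 0.744 and 0.659 CPM in the mature ones. The 95% Wilson intervals of 6 shares of reads, those of 29 to 32 nt, uridine at position 1, adenine at position 10 among reads without uridine at position 1, structured RNA matches and LINE-1 on each strand, were at most 0.154 percentage points to either side. Intervals of other shares were not computed. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. To look for a library deposited more than once, libraries of one group were compared over their counts, and no pair agreed within counting noise (chi-square of 12.4 to 47.7 per sequence). Repeat libraries of one testis can differ as much, so this does not show separate animals, and each library was counted as a sample because the labels list it as one.

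Changed sequences were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test on the counts. Scaling used TMM factors over the table totals, low counts were removed by filterByExpr with its defaults, and a Benjamini-Hochberg adjusted p under 0.05 made a call. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The test was checked on simulated counts for 31788 sequences with the means and totals of this comparison. It called 4.55% of the sequences changed 2-fold, 55.1% of those changed 4-fold and 92.3% of those changed 8-fold, and 6.48% of its calls were not among the changed sequences. The simulation gave all sequences the same dispersion and both groups the same means, apart from 200 sequences changed in random directions. In the data many more sequences were called and the TMM factors differed between the groups. The simulated rates therefore do not estimate power or false calls in this comparison. TMM and library totals gave different splits of calls, so both are printed.

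Shares of reads were compared by an exact two-sided permutation test of the difference of group means, which cannot give a p below 0.1 with 3 against 3 libraries. The tests were on the share of reads of 29 to 32 nt, the mean length, uridine at position 1, adenine at position 10 and the number of distinct sequences. The share of the 100 most abundant sequences and of matches to structured RNAs was tested likewise. The planned test of ping-pong overlaps needed no positions: a read counted when its first 10 nt were the reverse complement of the first 10 nt of another sequence in its library. The share of such reads minus the mean share with the 10 nt window shifted by 1 to 5 nt is called the 10 nt excess. On 22000 simulated random sequences with 18.2% planted pairs this gave 18.0%. The libraries hold many more sequences, most of which begin with uridine. The simulation therefore checks the computation and does not show how many pairs are recovered here.

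Structured RNAs were a hand-written list of 10 conserved mammalian sequences, of which 5 were tRNAs and the others 5S and 5.8S rRNA, U1 and a pair of Y RNAs. A match was exact. A longer list of 17 RNAs with up to 2 mismatches was added after the data were seen, and it is the one used wherever structured RNA matches were left out. Neither list held 28S rRNA or a snoRNA, so a sequence without a match can still be a fragment of such an RNA. A hand-written part of 28S rRNA of 77 nt, added after the data were seen, matched 20 sequences exactly, with 0.0909% ± 0.0125 of immature and 0.00438% ± 0.00211 of mature reads (SD, n = 3, exact permutation p = 0.1), and these were not left out. Sequences resembling the LINE-1 retrotransposon were also sought only after the data were seen. The best ungapped BLOSUM62 score of 8 codons in any frame was computed against a hand-written part of human LINE-1 ORF2p, with a minimum of 34, and against the reversed protein as a control. In simulation this found 28% of antisense pieces with 70% of residues kept and called 0.0175% of random sequences, so it gives relative shares and not the LINE-1 content.

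The named sequences followed a rule fixed before the data were examined: with neither positions nor genes in the table, 10 sequences in each direction were taken. They had the highest mean CPM among called sequences whose 3 values in one group all lay above the 3 of the other. A further 5 immature-high sequences without a structured RNA match were chosen after their values were seen, and so were the most abundant sequences named. Single values for one of the listed tRNAs and its fragments are not reported here.

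The alternatives were other normalizations, DESeq2 1.42.0, other filters, a replicate block, leaving out each library, counting each distinct sequence once, leaving out the 100 most abundant sequences, other length classes and thinning. Leaving out structured RNA matches, the tests of LINE-1 and of shared 5′ ends, the thinned tests of changed sequences and of the 10 nt excess and sums over the first 20 nt were chosen after seeing the data. No horse genome sequence was used here, so the planned tests of piRNA loci, of genes and gene lists, of genic and intergenic shares and of chromosome shares were not run. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, numba 0.67.0 and Biopython 1.88 were used.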

Results

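Small RNAs of 25 to 32 nt that had been called as piRNAs were counted in 3 libraries of immature testis and 3 libraries of mature testis of the Mongolian horse. piRNAs are small RNAs bound by PIWI proteins in germ cells, where they guide the silencing of transposons. The series was set up to follow piRNAs during the development of the testis and spermatogenesis. The immature libraries held 1382083 to 2347351 piRNA reads and the mature libraries 4032042 to 4550970. These totals count only the called piRNAs of the deposited table, which its name labels as newly found. The comparison throughout is mature against immature testis, and a p of 0.1 is the smallest that the exact permutation test can give with 3 libraries in each group.

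The piRNA pool of mature testis was made of longer sequences than that of immature testis. Reads of 29 to 32 nt made up 71.5% ± 0.957 (SD, n = 3) of the pool in mature testis and 36.1% ± 2.9 in immature testis (exact permutation p = 0.1). In immature testis the most frequent length was 27 nt, with 26.4% ± 1.58 of reads, followed by 26 nt with 20.7% ± 0.761. In mature testis these lengths held 10.6% ± 0.462 and 7.88% ± 0.537, and the most frequent lengths were 30 nt (24.9% ± 0.125) and 29 nt (24.3% ± 2.03). The mean length was 27.9 nt ± 0.122 in immature and 29.1 nt ± 0.0537 in mature testis (exact permutation p = 0.1). Each mature library lay above each immature library in both measures. With each distinct sequence counted once, the share of 29 to 32 nt was 57.6% ± 1.04 in mature and 26.6% ± 0.38 in immature testis. Without structured RNA matches the share of reads was 71.0% ± 0.723 in mature and 27.8% ± 0.873 in immature testis.

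**Figure D1:**
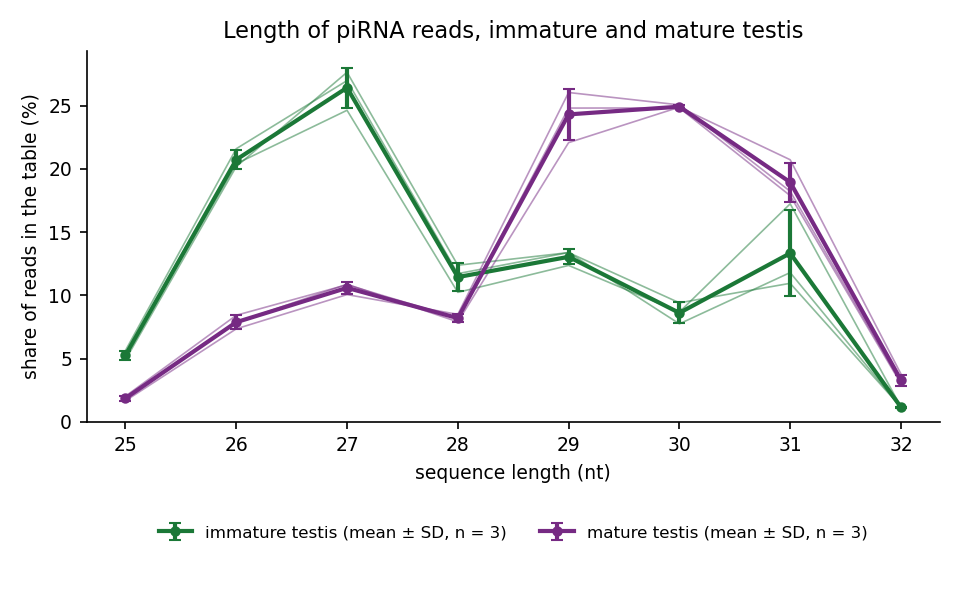
Share of reads in the table (%) at each sequence length (nt) in immature and mature testis, with thin lines for single libraries and points for the mean ± SD of 3 libraries. Immature testis peaks at 27 nt (26.4%), with a further peak at 31 nt (13.3%), and mature testis at 29 to 30 nt (24.3% and 24.9%).

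Fragments of tRNAs took a larger part of the pool in immature testis. Exact matches to the 10 structured RNAs made up 7.34% ± 1.98 of reads in immature and 0.544% ± 0.428 in mature testis (SD, n = 3, exact permutation p = 0.1). tRNA-Gly-GCC, a glycine tRNA, contributed 6.43% ± 1.65 in immature and 0.474% ± 0.413 in mature testis, from 28 distinct sequences. Both mature means rested on replicate 1, and without it they were 0.298% for all exact matches and 0.237% for tRNA-Gly-GCC. The share of 5S rRNA was 0.0128% ± 0.000993 in immature and 0.00218% ± 0.000428 in mature testis. For tRNA-Lys-CTT, with 9 sequences, the shares did not separate (exact permutation p = 0.3), and tRNA-His-GTG and RNY1 were seen with 5 sequences and 1 sequence. No exact match to tRNA-Val-CAC, 5.8S rRNA, U1 or RNY4 was among the 4936717 sequences. With up to 2 mismatches and 17 RNAs, a list chosen after the data were seen, the shares were 13.4% ± 3.17 and 2.20% ± 1.19. In that list 5S rRNA made up 0.522% ± 0.207 of immature and 0.128% ± 0.0263 of mature reads, and 5.8S rRNA, with 300 sequences, 0.0763% ± 0.0295 and 0.00539% ± 0.000795 (exact permutation p = 0.1 for each). tRNA-Lys-CTT, with 97 sequences, separated the groups there, at 0.00384% ± 0.000533 and 0.00199% ± 0.000332 (exact permutation p = 0.1). U1 was found with 95 and RNY4 with 90 sequences, and the shares of RNY4 did not separate (exact permutation p = 1). In the same list tRNA-Glu-TTC made up 0.678% ± 0.117 of immature and 0.585% ± 0.0897 of mature reads, a difference within the spread (exact permutation p = 0.4). As a share of distinct sequences rather than of reads, exact matches were rare in both groups, with 0.0062% ± 0.00111 in immature and 0.00466% ± 0.000397 in mature testis.

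Uridine at position 1, the usual first base of primary piRNAs, was found in 89.8% ± 0.611 of reads in mature and in 75.5% ± 1.91 in immature testis (SD, n = 3, exact permutation p = 0.1). Reads starting with guanosine made up 13.3% ± 2.6 in immature and 2.96% ± 0.644 in mature testis. Among reads of 31 nt, the length of the leading tRNA-Gly-GCC fragments, 37.0% ± 6.38 began with uridine in immature and 88.8% ± 3.36 in mature testis. At 27 nt the values were 81.9% ± 0.992 and 86.6% ± 0.505. Without structured RNA matches, 83.9% ± 1.55 of immature and 90.4% ± 0.139 of mature reads began with uridine, and 3.64% ± 0.731 and 2.24% ± 0.0523 with guanosine. With each distinct sequence counted once, the shares with uridine were 84.0% ± 0.913 and 85.0% ± 0.324, a difference of 1.07 percentage points.

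Adenine at position 10 and a 10 nt overlap between 5′ ends are marks of the ping-pong cycle, in which the cut made by one piRNA sets the 5′ end of another. The order of the groups in both marks depended on how sequences were weighted. Among reads without uridine at position 1, adenine stood at position 10 in 43.5% ± 3.28 in mature and 24.3% ± 2.71 in immature testis (SD, n = 3, exact permutation p = 0.1). Counting each distinct sequence once turned this to 36.6% ± 0.604 in mature and 44.7% ± 2.12 in immature testis. Without the 100 most abundant sequences of each library the shares were 41.0% ± 1.28 and 41.7% ± 2.09 (exact permutation p = 0.8). Without structured RNA matches they were 47.0% ± 1.55 and 41.2% ± 3.23. Over all reads, adenine at position 10 made up 30.4% ± 0.62 in mature and 28.04% ± 1.02 in immature testis, and 29.2% ± 0.255 and 32.03% ± 0.706 with each distinct sequence counted once. Over all immature reads guanine was the more frequent base there, with 33.8% ± 1.94, but without structured RNA matches it made up 24.3% ± 0.915 against 32.1% ± 0.859 for adenine, and with each distinct sequence counted once 23.6% ± 0.52. The shares of adenine were not compared with a background share.

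The 10 nt excess was 14.0 ± 1.06 percentage points of reads in mature and 10.4 ± 1.17 in immature testis (SD, n = 3, exact permutation p = 0.1). With each distinct sequence counted once it was 10.1 ± 0.337 in mature and 15.4 ± 0.989 in immature testis. Without structured RNA matches the read-weighted values were 14.8 ± 0.794 and 15.9 ± 0.917 (exact permutation p = 0.2). A second measure, the product of read shares over complementary 10 nt ends divided by its expectation from base composition, was 7.88 ± 0.793 in mature and 4.28 ± 0.423 in immature testis, and without structured RNA matches it was 7.84 ± 0.807 and 4.13 ± 0.373 (exact permutation p = 0.1). With the window shifted by 1 to 10 nt the same measure ran from 2.02 to 4.22 in mature and from 2.11 to 3.73 in immature testis, and in immature replicate 1 it was 4.68 at a shift of 3 nt, above 4.61 without a shift. For distinct sequences that measure was 3.15 ± 0.173 and 2.91 ± 0.291 (exact permutation p = 0.5).

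**Figure D2:**
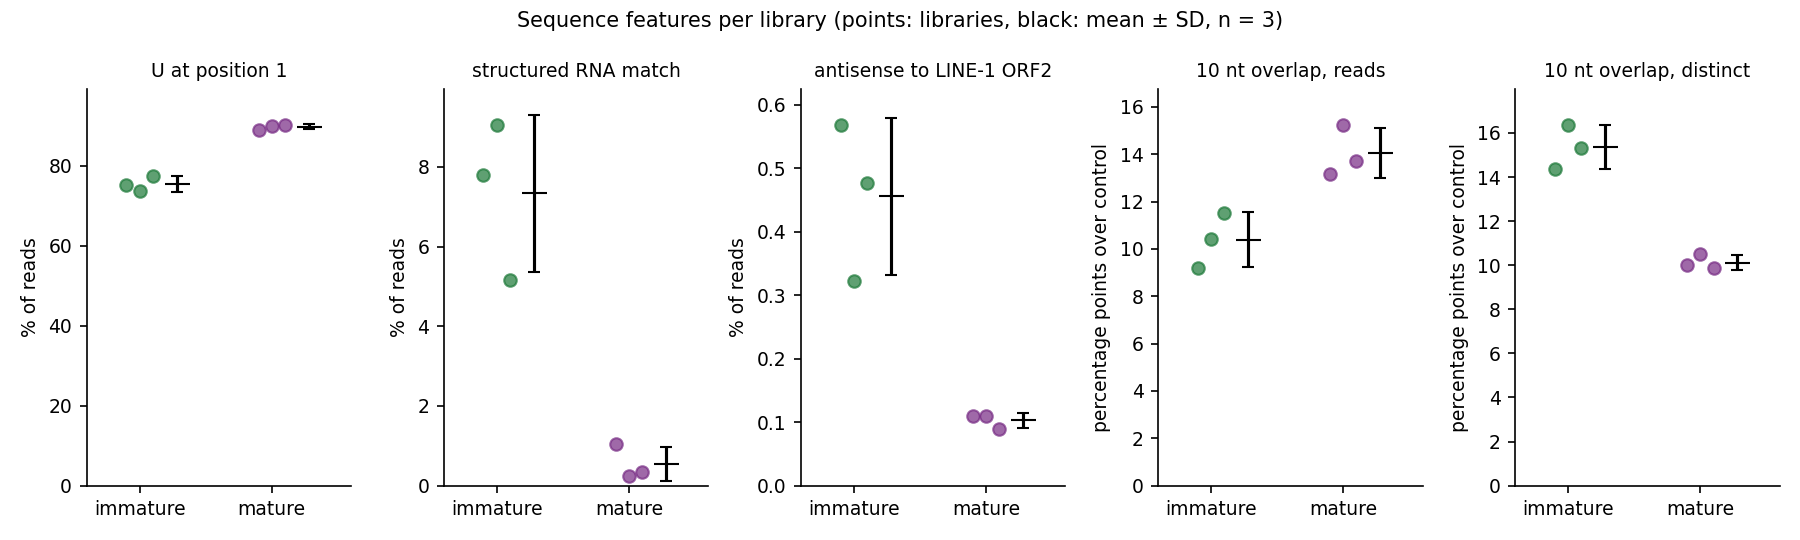
Features of the piRNA pool per library in immature and mature testis, each panel with its own vertical axis from 0: share of reads (%) with uridine at position 1, with an exact structured RNA match and antisense to the LINE-1 retrotransposon (0.456% in immature and 0.103% in mature testis, a feature chosen after the data were seen), and the 10 nt excess (percentage points over the shifted control) weighted by reads and with each distinct sequence counted once. Points are libraries and black marks the mean ± SD of 3 libraries; the 10 nt excess is higher in mature testis by reads (14.0 against 10.4) and higher in immature testis by distinct sequences (15.4 against 10.1).

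At equal numbers of called piRNA reads, which are not equal sequencing depth, the immature pool held more different sequences than the mature pool. After thinning every library to 1382083 such reads, 850614 ± 41531 distinct sequences were found in immature and 497545 ± 15171 in mature testis (SD, n = 3, exact permutation p = 0.1). As deposited, with fewer reads in the immature libraries, the numbers were 1023890 ± 233368 and 1136671 ± 8750 (exact permutation p = 0.4). That difference of 112781 sequences rested on single immature libraries, being 22344 without replicate 1, 71507 without replicate 3 and 244493 without replicate 2. The 100 most abundant sequences held 13.8% ± 3.06 of reads in immature and 7.87% ± 0.933 in mature testis (exact permutation p = 0.1). Without structured RNA matches the order turned, with 3.11% ± 0.544 in immature and 6.86% ± 0.172 in mature testis. With structured RNA matches included, the 1000 most abundant sequences held 19.1% ± 3.12 and 19.4% ± 0.846 (exact permutation p = 0.8).

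Sequences present in all 3 libraries of one group and in none of the other numbered 146093 for mature and 40269 for immature testis. The other 18 ways to choose 3 of the 6 libraries gave a mean of 3664 and at most 8470 such sequences. Each of these choices mixes libraries of both groups, so a difference between the groups lowers their numbers and they give no chance level. Requiring at least 3 reads in each library and at most 1 read in total in the other group left 52886 and 7050. The larger totals of the mature libraries favour detection there, so the numbers do not rank the groups.

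Single sequences separated the groups into a pool typical of mature and a pool typical of immature testis. Of 31788 tested sequences, edgeR with TMM factors called 9648 changed at an adjusted p under 0.05, of which 2672 were higher in mature and 6976 higher in immature testis. With library totals in place of TMM factors it called 31175, of which 24713 were higher in mature and 6462 in immature testis. All of the 2672 and 6462 of the 6976 were called in the same direction on both scales. Library totals raise the log2 fold changes, so mature-high calls were bound to keep their direction, and their agreement is no support for them. The share of calls that were higher in mature testis was 27.7% with TMM and 79.3% with library totals. The median log2 fold change moved from 0.62 to 3.15, a shift of 2.52, and directions on the TMM scale are relative to it. Sequences called higher in mature testis took 8.47% ± 0.259 of mature and 0.302% ± 0.143 of immature reads, and those called higher in immature testis took 23.8% ± 2.79 of immature and 2.49% ± 0.841 of mature reads (SD, n = 3). With TMM factors 88.4% of the mature-high sequences were of 29 to 32 nt, against 27.2% of the immature-high and 73.2% of those not called. Of all tested sequences 64.4% were of this length. With library totals the share was 74.98% of mature-high and 25.2% of immature-high sequences, so the mature-high share depended on the scale. With TMM factors uridine at position 1 was found in 91.1% of mature-high and 82.1% of immature-high sequences. It was found in 92.0% of all tested sequences and 95.2% of those not called. With library totals it was found in 94.8% of mature-high, 81.3% of immature-high and 92.8% of the sequences not called, so the order of mature-high and all tested sequences turned with the scale. Matches to structured RNAs numbered 463 (6.64%) among the immature-high and 0 among the mature-high sequences with TMM factors. With library totals they numbered 419 (6.48%) and 9 (0.0364%), and their share of all tested sequences was 1.49%. The mature-high count was 1773 without immature replicate 1, 1773 without immature replicate 3 and 6053 without immature replicate 2, and the count of all calls was 15014 without immature replicate 2. The filter was run again on the libraries left, so 52925, 52980 and 51730 sequences were tested, in the same order. These counts are therefore not directly comparable with those from 31788 tested sequences. Upper quartile factors gave 13822 mature-high calls and DESeq2 gave 4033. With all libraries thinned to the smallest total, edgeR gave 770 mature-high and 2805 immature-high calls among 13325 tested sequences. A filter at 10 CPM in 3 libraries left 2212 calls among 9322 tested sequences, and without a filter beyond 6 reads there were 86206 among 294186.

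**Figure D3:**
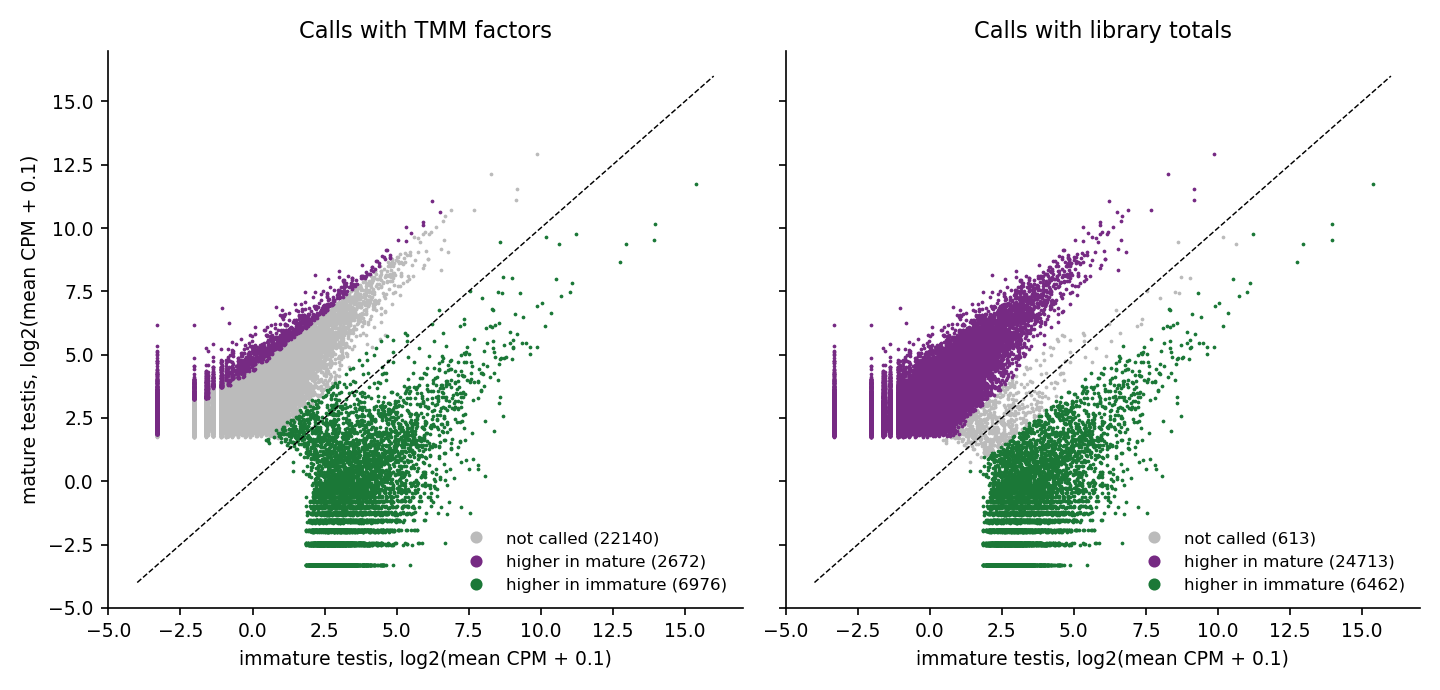
Mean level in immature (horizontal) and mature testis (vertical), both as log2(mean CPM + 0.1), of the 31788 tested sequences, coloured by the edgeR call with TMM factors (left) and with library totals (right); the dashed line marks equal CPM. The sequences form a cloud above and a cloud below the line, and the change of scale moves the upper cloud from mostly not called to 24713 sequences called higher in mature testis.

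Among sequences higher in mature testis, the most abundant by the fixed rule was uniq_5153807 (TAATAGAGACTGTTGAAGGATGAACTCAAC), at 2155 ± 715 CPM in mature and 74.1 ± 86.2 CPM in immature testis (SD, n = 3). Its log2 fold change was 2.24 ± 0.63 (SE) with TMM factors (edgeR adjusted p = 0.00179) and 4.87 ± 0.83 with library totals (adjusted p = 2.97e-08). It was not called with DESeq2 (adjusted p = 0.152) or without immature replicate 1 (edgeR adjusted p = 0.104), and its log2 fold change was 4.72 without immature replicate 3; over all alternatives its adjusted p ran from 2.97e-08 to 0.185. uniq_1435444 (TATGACTAAAACTGACTGGAGGGCTGGTT) stood at 1595 ± 266 CPM in mature and 90.2 ± 45.2 CPM in immature testis. uniq_5212563 (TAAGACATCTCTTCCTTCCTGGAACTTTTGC) stood at 1201 ± 24.9 and 60.5 ± 40.3 CPM, and uniq_2919082 (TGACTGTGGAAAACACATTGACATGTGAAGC) at 1103 ± 61.8 and 59.8 ± 11.1 CPM. The other 6 were uniq_5218759, uniq_4921673, uniq_4183634, uniq_3572800, uniq_3673441 and uniq_2695404, with mature means of 553 to 1044 CPM and immature means of 24.6 to 45.0 CPM. All 10 began with uridine and were of 29 to 31 nt, and their CPM ratios of mature to immature testis ran from 17.7 to 29.1. Leaving out 1 immature library moved 6 of these ratios by over 1.5 times. Without replicate 3 the ratio of uniq_5153807 was 80.9, and without replicate 2 the ratios were 32.3 for uniq_5212563, 31.7 for uniq_4921673, 29.7 for uniq_3572800, 34.7 for uniq_3673441 and 35.6 for uniq_2695404. With TMM factors their adjusted p ran up to 0.0357, and 0 of the 10 stayed under 0.05 with edgeR after the filter at 10 CPM, where the adjusted p reached 0.232. Without immature replicate 3, 4 of the 10 stayed under 0.05.

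All 10 sequences named for immature testis were 5′ fragments of tRNAs that start at the first base of the tRNA, 7 of them from tRNA-Gly-GCC. The most abundant sequence of the table, uniq_2076883 (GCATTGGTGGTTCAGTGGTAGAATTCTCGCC), a tRNA-Gly-GCC fragment of 31 nt, stood at 42860 ± 15381 CPM in immature and 3421 ± 3626 CPM in mature testis (SD, n = 3), a ratio of 12.5. Its log2 fold change was -6.21 ± 0.93 (SE) with TMM factors (edgeR adjusted p = 9.83e-11) and -3.65 ± 0.92 with library totals (adjusted p = 0.0001). The mature level rested on replicate 1, where tRNA-Gly-GCC took 0.948% of reads against 0.188% and 0.285% in the other mature libraries. Without that library the ratio was 32.04 and the log2 fold change -7.54, and without immature replicate 2 the log2 fold change was -5.32. The further tRNA-Gly-GCC fragments uniq_3790290, uniq_2080573, uniq_3790284, uniq_2069824, uniq_2789082 and uniq_2092732 were 9.54 to 21.1 times higher in immature testis. Without mature replicate 1 the ratios were 33.2 for uniq_3790290, 29.4 for uniq_3790284, 15.1 for uniq_2069824 and 31.6 for uniq_2789082, each over 1.5 times the ratio of all libraries, and without immature replicate 1 the ratio of uniq_2080573 was 13.7 in place of 21.1. uniq_4708970, from tRNA-Glu-TTC, was 2.72 times higher in immature testis. Of the 10 sequences, 9 were also called with library totals, and the other had an edgeR adjusted p of 0.0831 on that scale. Not every structured RNA match was lower in mature testis: uniq_4708991, chosen after its values were seen, stood at 2227 ± 306 CPM in mature and 568 ± 459 CPM in immature testis (314 CPM without immature replicate 2), and was called higher in mature testis with library totals (edgeR adjusted p = 0.00801) and not called with TMM factors (adjusted p = 0.507). It differs from uniq_4708970 in its last base only. uniq_4072286, chosen likewise, has the sequence of uniq_2076883 with another first base and an added last base. It stood at 2960 ± 2682 CPM in mature and 579 ± 391 CPM in immature testis, a wide spread in both groups. With library totals it was called higher in mature testis (edgeR adjusted p = 0.00204), and with TMM factors it was not called (adjusted p = 0.73).

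Because all of those were tRNA fragments, the 5 most abundant immature-high sequences without a structured RNA match were also taken, chosen after their values were seen. uniq_222460 (TTGCTGAGGAAGACTGGCCCTGAGCTA) stood at 935 ± 409 CPM in immature and 39.1 ± 24.5 CPM in mature testis (SD, n = 3). uniq_5134990 (TGGAAGTCGGAATCCGCTAAGGAGTGT) stood at 791 ± 109 and 32.7 ± 16.6 CPM, and it matched without a mismatch a part of 28S rRNA, an RNA that neither list of structured RNAs held. uniq_170669 stood at 786 ± 549 CPM in immature testis and uniq_173892 at 716 ± 616 CPM. These sequences share a stretch of 24 nt and are not independent of each other, and both were highest in immature replicate 1, at 1417 and 1428 CPM, against 341 to 524 CPM in the other immature libraries. The last was uniq_3130864, and the ratios of immature to mature testis over the 5 sequences ran from 14.8 to 24.2. Without immature replicate 1 the ratio was 11.9 for uniq_170669 and 8.17 for uniq_173892, and without mature replicate 2 it was 36.7 for uniq_222460. Each was called on both scales. The most abundant sequence of mature testis, uniq_274482 (TGGATAAATAAATTGTGGTATATTTCTGCA), also chosen after its values were seen, stood at 7824 ± 660 CPM in mature and 925 ± 815 CPM in immature testis. The immature mean rested on replicate 2, and without it the mean was 484 CPM and the ratio of mature to immature testis 16.2 in place of 8.46. It was called with library totals (log2 fold change 3.08, edgeR adjusted p = 0.000202) and not with TMM factors (0.56, adjusted p = 0.527).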

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

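Left-out structured RNA matches, sums over 5′ ends, thinned tests of changed sequences and of the 10 nt excess, LINE-1 and shared 5′ ends were chosen after seeing the data. Leaving out each library kept the direction in 72 of 72 comparisons of shares, lengths and numbers of sequences. Except for the number of distinct sequences, the groups did not overlap in these comparisons. Leaving out a library could not have turned the direction there, so the count is no evidence for it. With 2 against 3 libraries no permutation p can pass a threshold. Of 36 other values 21 kept their direction, among them all for length, uridine at position 1, structured RNA matches and LINE-1 antisense reads, and 15 turned. In percentage points, mature minus immature, counting each distinct sequence once gave -8.12 for adenine at position 10 among reads without uridine at position 1, -2.85 for it over all reads, -5.24 for the 10 nt excess and -0.0568 for LINE-1 sense reads. Without the 100 most abundant sequences the first, the second and the last of these were -0.733, -2.48 and -0.00302. Without structured RNA matches the values were -8.2 for adenine among distinct sequences, -1.05 over all reads, -1.12 for the 10 nt excess and 3.75 for the 100 most abundant sequences. For the 1000 most abundant, with those matches included, the value was 0.387. Thinning gave -6.33 for the 10 nt excess and -0.0584 for LINE-1 sense reads among distinct sequences, and -353069 for the number of distinct sequences. The cause of the turns was not tested.

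For changed sequences the counts are all calls, then higher in mature, then higher in immature where they moved. They were 31175 and 24713 with library totals, 20642 and 13822 with upper quartile factors, and 4033 higher in mature with DESeq2, which left 18 adjusted p-values undefined. Without a filter they were 86206, 28866 and 57340 from more sequences tested, and at 10 CPM 2212, 430 and 1782 from fewer. At thinned totals they were 3575, 770 and 2805 from 13325 tested sequences. Sums over the first 20 nt gave 17113, 5370 and 11743, and with library totals 32380, 21820 and 10560. Leaving out each library gave 11035 to 15014 calls, 1773 to 6053 higher in mature and 8943 to 10094 higher in immature testis. The filter was run again each time, and 29005 to 52980 sequences were tested. A replicate block gave 7484 calls, 693 of them higher in mature testis and 6791 in immature testis. Deviations of same-numbered libraries from their group means correlated at 0.0161, -0.0728 and 0.0101, and not every library correlated best with its own number. These values show no pairing by number. They cannot exclude it, since levels correlated between the groups at -0.382 to -0.0440 (Pearson, log2 CPM) and the groups shared little signal. The named sequences kept their direction under each alternative that tested them, and were called in 111 of 120 tests without a library and 151 of 170 others. Of the 10 named for mature testis, 4 stayed under 0.05 at thinned totals (highest edgeR adjusted p 0.168). Without mature replicate 3, 8 of them stayed, and with the replicate block 9. The 5 immature-high sequences chosen later were called in 30 of 30 tests without a library and 45 of 45 others. RLE factors, a 2-fold threshold and left-out structured RNA matches changed no count by over 1.5 times.

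Sequences found in one group only fell to 7050 for immature and 52886 for mature testis under the stricter rule, and leaving out each library gave 44600 to 97320 and 152008 to 242407, where the moves by over 1.5 times came from leaving out a library of the same group, which loosens the rule. Not run for lack of positions: the alternatives for loci, genes, gene lists, genic shares, chromosome shares and uniquely placed overlaps. Those for normalized values did not apply to counts. Depth limits presence: a count of 0 allows up to 2.17 CPM in immature and 0.744 CPM in mature libraries.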

Other observations

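The tests of LINE-1 reads, of carry-over and of shared 5′ ends were chosen after the result was seen, as was the set of mature-abundant sequences.

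Reads antisense to LINE-1, a retrotransposon that piRNAs silence in germ cells, were more frequent in immature testis. They made up 0.456% ± 0.124 of reads in immature and 0.103% ± 0.0123 in mature testis (SD, n = 3, exact permutation p = 0.1). The leading antisense sequences in immature testis were uniq_321222 (CCATTGAGTATGATGTTGGCTGTGGGT) at 90.5 CPM and uniq_319261 (TAAGATCATGTCGTCTGCAAACAGCGAGA) at 88.3 CPM, which made up 1.99% and 1.94% of the antisense reads there. Of sequences called higher in immature testis 71 (1.02%) were antisense to LINE-1, against 1 (0.0374%) of those higher in mature testis. With library totals the numbers were 68 (1.05%) and 15 (0.0607%), and over all tested sequences the share was 0.274%. Sense reads went the other way, at 0.302% ± 0.0795 in immature and 1.20% ± 0.0985 in mature testis. In mature testis uniq_274482 alone held 65.3% of them, and without the 100 most abundant sequences the difference was -0.00302 percentage points. The reversed protein, the control, gave 2478 sense matches against 8729 and also separated the groups, at 0.0373% ± 0.0060 of immature and 0.0785% ± 0.00564 of mature reads (SD, n = 3, exact permutation p = 0.1). The search used part of a human protein, so these shares are not the LINE-1 content of the pool.

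For the antisense difference, chance similarity, a few abundant sequences and unequal totals of called piRNA reads, which are not sequencing depth, were tested. The reversed protein gave a difference of -0.0827% of the observed one, with 1024 antisense matches against 13591. With each distinct sequence counted once, the lowest immature library still lay 0.156 percentage points above the highest mature library, and after thinning 0.168. These values argue against each of the 3 as the whole cause. A larger part of transposon-directed piRNAs in immature testis is a hypothesis in line with this, found on the same data, and the age of the testis itself was not tested apart from the group.

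The split of changed sequences depended on scaling. The mean TMM factor was 6.06 times higher in mature than in immature testis, and a bound of 1.5 was set for each explanation. The ratio was 5.50 without the 100 most abundant sequences of each library, 7.94 with all libraries thinned to the smallest total, and 5.34 without structured RNA matches. The thinned ratio argues against unequal totals of called piRNA reads as the whole cause. The 100 most abundant sequences held 13.8% of immature and 7.87% of mature reads, and structured RNA matches 13.4% and 2.20%. Leaving out parts of this size changes little but the totals. The bound could therefore hardly have been met, and these ratios add no test beyond the shares themselves. Shares of this size are too small to be the whole cause of a ratio of 6.06. Sequencing depth itself could not be matched. The tested sequences held 49.5% to 51.4% of mature but 26.4%, 32.5% and 24.996% of immature reads, so a candidate explanation is that the immature pool is spread over many sequences too rare to test.

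Only 1 of the 10 splits of the 6 libraries into 3 against 3, the real one, gave as many as 9648 changed sequences, and the highest of the others gave 0 with edgeR (up to 187 at an unadjusted p under 0.05). That number of splits is too small for a share under 0.05. Each of the other splits mixes both groups, so a difference between the groups lowers their counts and they give no chance level.

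Over 378 sequences with at least 100 CPM in each mature library and no structured RNA match, the median level in immature replicates 1, 2 and 3 was 2.63%, 11.2% and 7.08% of the mature level. Scaling of the library does not account for it, since the median ratio of replicate 2 to the others was 2.17 for these sequences and 0.827 for immature-high sequences, 2.63 times apart. Carry-over of mature reads would bring every abundant sequence alike, but 9 of the 378, each with at least 20 reads expected, had 0 or 1 read in replicate 2. Of the sequences with as many reads expected, 0 of 26 in replicate 1 and 0 of 196 in replicate 3 had so few, so carry-over stays open for those libraries. uniq_5153807, with 9363, 5612 and 12788 reads in the mature libraries, had 1 in replicate 2, which limits carry-over of it there to 0.11% of its mature level (95% Poisson interval, counting error only), and a biological difference between the immature testes was not tested.

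A further hypothesis was that donor variants explain the absent sequences: for 5 of the 9, a partner of equal length with 1 mismatch had at least 10 times as many reads in immature replicate 2. Partners with at least 10 reads were common, since 199 of the other 369 sequences had one, but the 5 partners all differed before the last base, which held for 7 of the other 369, a comparison chosen after the result was seen. The partner of uniq_5153807, uniq_4729505 (TAATAGAGACTGTTGAAGGATGAACGCAAC), differs by T26G, counted from 1 at the 5′ end, and had 0, 72 and 0 reads in the immature and 3, 1053 and 0 in the mature libraries. Several of the 9 overlap one another, so they are fewer than 9 independent cases, and donor variants in the absent sequences may instead be near-identical copies in the genome, which was not tested.

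The longer reads of mature testis were not only other sequences. At 1444 5′ ends, taken as the first 20 nt with at least 10 reads in each library and no structured RNA match, the mean length was 28.7 nt ± 0.0263 in mature and 28.1 nt ± 0.00315 in immature testis (SD, n = 3, exact permutation p = 0.1), a difference of 0.609 nt. Reads were longer in mature testis at 85.7% of these ends. All mature libraries lay above all immature ones at 53.5%, and the reverse held at 1.32%, where chance gives 5% for each direction at a single end. The ends were measured in the same libraries and are not independent. A length shift common to a whole library would move them together and was not told apart. With at least 5 or at least 20 reads the difference was 0.622 and 0.623 nt. The values fit the hypothesis that the same 5′ ends may be trimmed to different lengths in the testes, and the mechanism was not tested.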
